A study of Arabidopsis thaliana with 10 samples.

How the data were processed

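The data were 10 one-colour arrays of the Affymetrix type, 2 for each of 5 groups, hybridised with biotin-labelled cRNA made in 2 rounds of amplification, per the labels' protocols. The authors deposited 1 table with a linear intensity for each of 22810 probe sets on each array. The submitters' processing notes name MAS5, with no version or role. The scale is linear. Medians of the arrays, replicate 1 and 2, were 257 and 266.9 in unpollinated pistils, 267.3 and 266 at 0.5 HAP, 257.1 and 257 at 3.5 HAP, 272.2 and 269.6 at 8 HAP, and 253.9 and 251.5 in ovules. From these close medians a scaling common to the arrays was inferred; its method is unknown, and the values were used as scaled. The largest value was 19000 and 19170 on the ovule arrays and at most 14650 on the others. Every column was used.

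Probe sets were named only through the platform annotation and the gene table (assembly TAIR10.1, used for names and for the genome a gene belongs to). Of the probe sets 13513 named 1 gene, 503 named several and 8730 non-control ones had no gene name in these tables; 13436 of those naming 1 gene matched the gene table. No gene was named from a probe set with several names. Many well-known genes are therefore not named here, and gene lists are covered only in part.

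The 64 control probe sets and 1 probe set with no values were left out of the tests, leaving 22745. Values were taken as log2(value + 16), with no filter. limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend) was fitted to all 5 groups at once, with 5 residual and 6.106 prior degrees of freedom. Benjamini-Hochberg adjustment was applied over all tested probe sets and the threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 16) scale. The background level was the 95th percentile (136.5) of 27 Bacillus subtilis control probe sets, and RNA quality was read from 3' to 5' ratios of Arabidopsis control probe sets. With 2 arrays per group, the spread is mainly that borrowed across probe sets. Data with independent noise of the fitted spread were simulated for the 0.5 HAP comparison over 22745 probe sets. On the log2 scale 68 of them were changed by 0.5, 66 by 1 and 66 by 2. Of these 79.4%, 100% and 100% were recovered, and 12 unchanged probe sets were called. The real comparison has far more calls and its noise need not be independent, so these rates may not hold there.

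The comparisons, their tests, 20 gene lists and the rule for named genes were fixed before the data were examined. That rule took the 12 largest rises and 8 largest falls against unpollinated pistils, or 5 and 5 for a step between times. It was limited to probe sets naming 1 gene, past the threshold, with both arrays of one group apart from both of the other and the higher group above the median of all values. It also took up to 4 members of each list with the smallest adjusted p. Lists were counted by direction, and those with at least 3 measured genes were tested with camera at an inter-gene correlation of 0.01 and with an estimated one, adjusted over the 11 lists of a comparison. A gene with several probe sets was represented by the one with the highest mean. The sperm cell and senescence lists had 0 measured members. Symbol families of at least 6 genes, the 2 organelle genomes and a heat shock list were added after the data were examined, 40 sets in all.

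Alternatives were mean values over a gene's probe sets, 1 call of an overlap left unadjusted, quantile normalization, pseudocounts of 1 and 64, leaving out the dimmest 40% of probe sets, fits with only the pistil groups or only the 2 groups compared, no trend, a robust fit, a replicate block, centring on 3 reference genes and leaving out each array. Overlaps were compared with 20 simulations of unchanged groups. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. No genome was used and no coordinates are given.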

Results

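The series measured transcripts in Arabidopsis thaliana pistils, ecotype Columbia, before and during the growth of pollen tubes, and in unfertilised ovules. There were 5 groups of 2 arrays: unpollinated pistils, pollinated pistils collected at 3 times, given in hours after pollination (0.5 HAP, 3.5 HAP and 8 HAP), and ovules dissected from unpollinated pistils. Flowers were emasculated the day before pollination. Pollinated pistils were measured with their pollen and pollen tubes, so a rise against unpollinated pistils may come from pollen RNA, pistil tissue or both. Per the labels each replicate was a separate pool of pistils or ovules from many plants, so the p-values rest on the spread between such pools. A single spread per probe set was fitted over all 5 groups, though it was unequal. The SD of the log2 replicate difference was 0.23 in unpollinated pistils and 0.20 in ovules, against 0.12 to 0.15 in pollinated groups. The p-values may therefore understate the spread in comparisons with unpollinated pistils and overstate it between pollinated times. The 22745 non-control probe sets with values had medians between 251.5 and 272.2 per array, and 2 arrays per group limit the precision. Replicate arrays correlated at r between 0.99071 (unpollinated pistils) and 0.99722 (0.5 HAP) across probe sets, which are not independent replicates. Unpollinated replicate 2 stood apart in RNA quality: its log2 ratio of the 3' to the 5' actin control was 2.96, against 1.95 in unpollinated replicate 1 and 1.93 to 2.55 in the other 8 arrays. Values up to 136.5 lay within the range of bacterial control probe sets and are called background level here. Folds are on the log2(value + 16) scale, which understates the change of genes at that level. A fold with 1 mean at that level depends on the background and on the 16 added, so it gives no exact size or rank.

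The first comparison asked which transcripts differed between pistils at 0.5 HAP and unpollinated pistils. LTI30, a dehydrin, rose 19.2-fold, from 43.4 ± 0.601 to 1125 ± 36.3 (SD, n = 2; limma adjusted p = 4.84e-08), from a mean within the background level. AT3G07820, a polygalacturonase, rose 10.9-fold (log2 3.44, SE 0.248) and AT3G01270, a pectate lyase, 8.11-fold. AT5G45880, of the pollen Ole e 1 allergen family, rose from 502.8 ± 112 to 4027 ± 76 (SD, n = 2), and AT1G72290, a Kunitz-type protease inhibitor, rose 10.0-fold. AT1G55450, AT2G25510, AT3G26140, AT5G39880, AT1G10770, AT3G01240 and AT3G28750 rose between 7.11-fold (AT3G28750) and 10.1-fold (AT1G55450). In the other direction, ATHSP22.0, a small heat shock protein, fell (log2 -3.88), from 1285 ± 270 to 71.9 ± 8.73 (SD, n = 2; adjusted p = 1.27e-05). BCAT4, an enzyme of methionine-derived glucosinolate synthesis, fell 7.98-fold, and AT5G48570, an FKBP-type chaperone, 8.49-fold. AT4G38080, AT2G23540, AT2G07718 and the mitochondrial genes cox2 and nad4L fell between 7.93-fold (AT2G23540) and 13.2-fold (AT2G07718).

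Of the gene lists written before the data were examined, the pollen and pollen tube list rose at 0.5 HAP. Of its 55 members 7 were measured under a name, and 6 rose, also when adjusted over the list alone; 4 of the 6, ANX1, AT4G39110, AT2G21480 and AT5G45840, rose within the background level. The list passed camera at adjusted p = 6.2e-05 and missed it with an estimated correlation (adjusted p = 0.0682). ANX2, a receptor kinase of pollen tubes, rose 3.17-fold (log2 1.67, SE 0.124), and TUA1, a tubulin of pollen, rose 1.61-fold from an unpollinated level of 476.4. Among 6 measured stigma, style and transmitting tract genes, 3 rose and 1 fell: ARPN, a plantacyanin, rose 4.00-fold, AT3G12000, an S-locus related gene, 2.91-fold, and SPT, a bHLH factor of carpel margins, fell 1.77-fold. The list itself did not pass (adjusted p = 0.273). Both measured jasmonate genes rose, JMT by 2.96-fold and OPCL1 by 2.46-fold, as did both water stress genes, COR15A by 4.30-fold and COR47 by 1.96-fold. Of 4 touch, wound and pattern-triggered genes, WRKY22 (1.85-fold, within the background level) and WRKY53 (1.38-fold) rose, with a list adjusted p = 0.0391, or adjusted p = 0.232 with an estimated correlation; without 0.5 HAP replicate 2, unpollinated replicate 1 or unpollinated replicate 2 the list missed it (adjusted p = 0.0792, 0.0595 and 0.0793). The single measured gene of the anther, pollen coat and petal list, AT5G07230, rose 1.33-fold within the background level. Single arrays decided 3 of these calls. NGA1, the third stigma and style gene called higher, missed the threshold without 0.5 HAP replicate 1 or 2 (adjusted p = 0.105 and 0.104), without unpollinated replicate 2 (adjusted p = 0.0615) and with arrays centred on the reference genes (adjusted p = 0.112). WRKY53 missed the threshold without 0.5 HAP replicate 2 (adjusted p = 0.0588), and AT5G07230 without 0.5 HAP replicate 1 (adjusted p = 0.163) or unpollinated replicate 1 (adjusted p = 0.0728).

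In total 6880 probe sets changed at 0.5 HAP by limma with Benjamini-Hochberg adjustment, 3536 up and 3344 down, of which 457 rose and 230 fell at least 2-fold. The total was 4360 with arrays centred on 3 reference genes, and 3723 or 4047 without 0.5 HAP replicate 1 or 2. Without unpollinated replicate 2 it was 5995. The share of rises was 51.4% as deposited, 48.0% after quantile normalization and 54.2% with arrays centred on the reference genes. The median log2 difference over all probe sets was -0.020, or -0.050 without unpollinated replicate 1 and 0.014 without unpollinated replicate 2. Which direction prevailed thus depended on the processing.

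**Figure D1:**
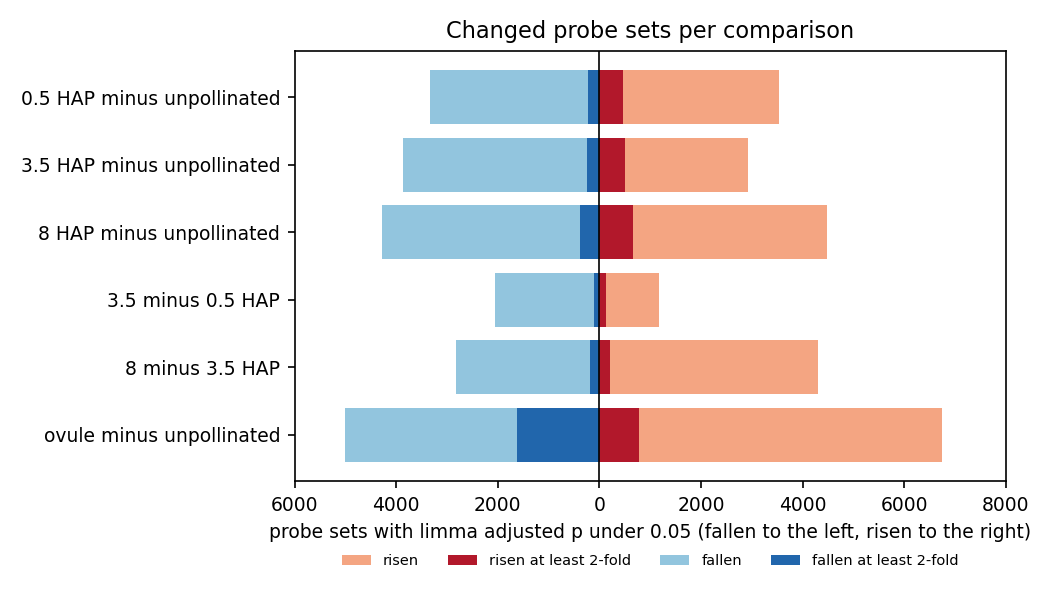
Probe sets past the limma threshold in each of the 6 comparisons, fallen to the left and risen to the right on a linear axis, with darker bars for those changed at least 2-fold. The ovule bar is the only one with more probe sets fallen (1622) than risen (778) at least 2-fold.

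The second comparison set pistils at 3.5 HAP against unpollinated pistils. AT3G07820 was now 21.8-fold higher (2822 ± 200 against 114.9 ± 20.4; SD, n = 2; adjusted p = 2.28e-07), and AT3G01270 16.7-fold. GH3.3, which conjugates auxin to amino acids, rose 16.5-fold, from 30.9 ± 1.95 to 759.7 ± 113 (SD, n = 2). AT5G07430, a pectinesterase, rose 12.7-fold, AT5G47000, a peroxidase, 13.7-fold, and AT3G26860, of the plant self-incompatibility S1 family, 13.3-fold. AT5G26700, AT2G25510, AT5G39880, AT3G28750, AT4G02250 and AT5G19580 rose between 13.2-fold (AT5G19580) and 16.7-fold (AT5G26700). ATHSP22.0 fell 17.7-fold and AT2G23540 13.7-fold. AT4G38080, AT2G07718 and AT2G07707 fell by log2 differences between -3.46 (AT2G07707) and -3.89 (AT2G07718), and the mitochondrial genes cox2, nad9 and nad4L fell between 9.99-fold (nad4L) and 12.7-fold (cox2).

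All 7 measured pollen list genes rose at 3.5 HAP (adjusted p = 2.58e-09, and adjusted p = 0.0159 with an estimated correlation), 3 of them within the background level. The others include ANX2 (6.77-fold) and AT5G45840, a receptor kinase (3.18-fold). AT5G07230, of the anther list, was at 79.96 ± 8.9 against 82.4 ± 6.93 in unpollinated pistils (SD, n = 2; adjusted p = 0.824). In the touch and wound list WRKY53 (2.27-fold), WRKY6 (1.52-fold) and WRKY22 (1.48-fold) rose, with a list adjusted p = 0.0114, or adjusted p = 0.147 with an estimated correlation. In the salicylate and pathogenesis-related list SAG101 rose 1.86-fold, while PDF1.4 (2.96-fold) and THI2.1 (1.17-fold) fell; the list did not pass (adjusted p = 0.885). Of 8 cell wall loosening genes 3 rose, including EXPA4 (1.66-fold) and EXPB3 (1.65-fold), and 3 fell, including XTH19 (2.01-fold) and XTH18 (1.83-fold), so the list as a whole did not pass (adjusted p = 0.885). WRKY22 missed the threshold without 3.5 HAP replicate 2 (adjusted p = 0.0631), as did THI2.1 (adjusted p = 0.0525), which also missed it with arrays centred on the reference genes (adjusted p = 0.377). EIN3, the only measured ethylene gene, had a log2 difference of 0.36 (SE 0.128, adjusted p = 0.0571).

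At 3.5 HAP 6796 probe sets changed, 2929 up and 3867 down, with 506 risen and 245 fallen at least 2-fold. With arrays centred on the reference genes the total was 4091 and the share of rises among calls moved from 43.1% to 56.4%; without 3.5 HAP replicate 1 or 2 the total was 4181 or 3981, and without unpollinated replicate 2 it was 5238.

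The third comparison set pistils at 8 HAP against unpollinated pistils. UF3GT, a glycosyltransferase of anthocyanin synthesis, rose 24.6-fold, from 131.6 ± 12.8 to 3608 ± 225 (SD, n = 2; adjusted p = 2.62e-10), and DFR, an enzyme of the same pathway and the only measured member of the flavonoid list, rose 7.06-fold. GH3.3 rose 21.9-fold and AT3G07820 20.9-fold. AT5G39880, AT1G49290, AT3G01270, AT3G28750, scpl38, AT2G25510, AT5G26700, AT5G47000 and AT1G10770 rose by log2 differences between 4.12 (AT1G10770) and 4.53 (AT5G39880). AT2G33850 fell 40.3-fold, from 2530 ± 7.34 to 47.2 ± 0.602 (SD, n = 2), a mean within the background level. AT4G19430 fell 8.27-fold. ATHSP22.0, AT2G07718, AT4G38080, AT2G23540, AT2G07722 and cox2 fell between 7.57-fold (cox2) and 13.0-fold (AT2G07718).

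All 7 measured pollen genes rose again at 8 HAP (adjusted p = 1.82e-07, and adjusted p = 0.0268 with an estimated correlation), 2 of them within the background level and ANX2 by 9.46-fold. All 5 measured photosynthesis genes fell, from 1.36-fold for RCA, rubisco activase, to 1.52-fold for PSAN, a photosystem I subunit (list adjusted p = 0.00576, or adjusted p = 0.433 with an estimated correlation; adjusted p = 0.0514 without unpollinated replicate 1). Of 3 gibberellin genes, all receptors, GID1A (2.13-fold) and GID1B (1.63-fold) fell and GID1C had a log2 difference of -0.21 (adjusted p = 0.0708), though 3 passed when adjusted over the list alone. The list passed at adjusted p = 0.0383, or adjusted p = 0.274 with an estimated correlation, and missed without 8 HAP replicate 1 (adjusted p = 0.0638) or unpollinated replicate 1 (adjusted p = 0.0743). In the embryo sac list 4 of 6 genes fell, including EC1.2 (2.60-fold) and EC1.5 (1.83-fold), genes of the egg cell, and AGL62 rose 1.58-fold within the background level; the list did not pass (adjusted p = 0.229). Of 6 stigma, style and transmitting tract genes 2 rose and 3 fell, and the list did not pass (adjusted p = 0.541): CES, a bHLH factor of the transmitting tract, fell 4.47-fold and AT3G12000 4.56-fold, while ARPN rose from 1247 ± 281 to 2485 ± 131 (SD, n = 2). BAN, a proanthocyanidin enzyme of the ovule's inner integument, rose 4.43-fold, and INO, of the outer integument, fell 1.28-fold. GI, the only measured clock gene, fell 2.28-fold. COR15A (2.16-fold) and COR47 (1.97-fold) fell, and PRL, a replication licensing factor and the only measured cell cycle gene, rose 1.28-fold. INO missed the threshold with arrays centred on the reference genes (adjusted p = 0.123), without 8 HAP replicate 1 (adjusted p = 0.101) and without unpollinated replicate 1 (adjusted p = 0.0535). PRL missed it without the same arrays (adjusted p = 0.13 and 0.0511).

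At 8 HAP 8763 probe sets changed, 4483 up and 4280 down, with 659 risen and 376 fallen at least 2-fold. The total was 5610 without 8 HAP replicate 2 and 7953 without unpollinated replicate 2. The share of rises was 51.2% as deposited, 46.3% after quantile normalization and 59.1% with arrays centred on the reference genes. Without the dimmest 40% of probe sets it was 49.5%. The median log2 difference over all probe sets was -0.012, or -0.043 without unpollinated replicate 1 and 0.024 without unpollinated replicate 2.

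**Figure D2:**
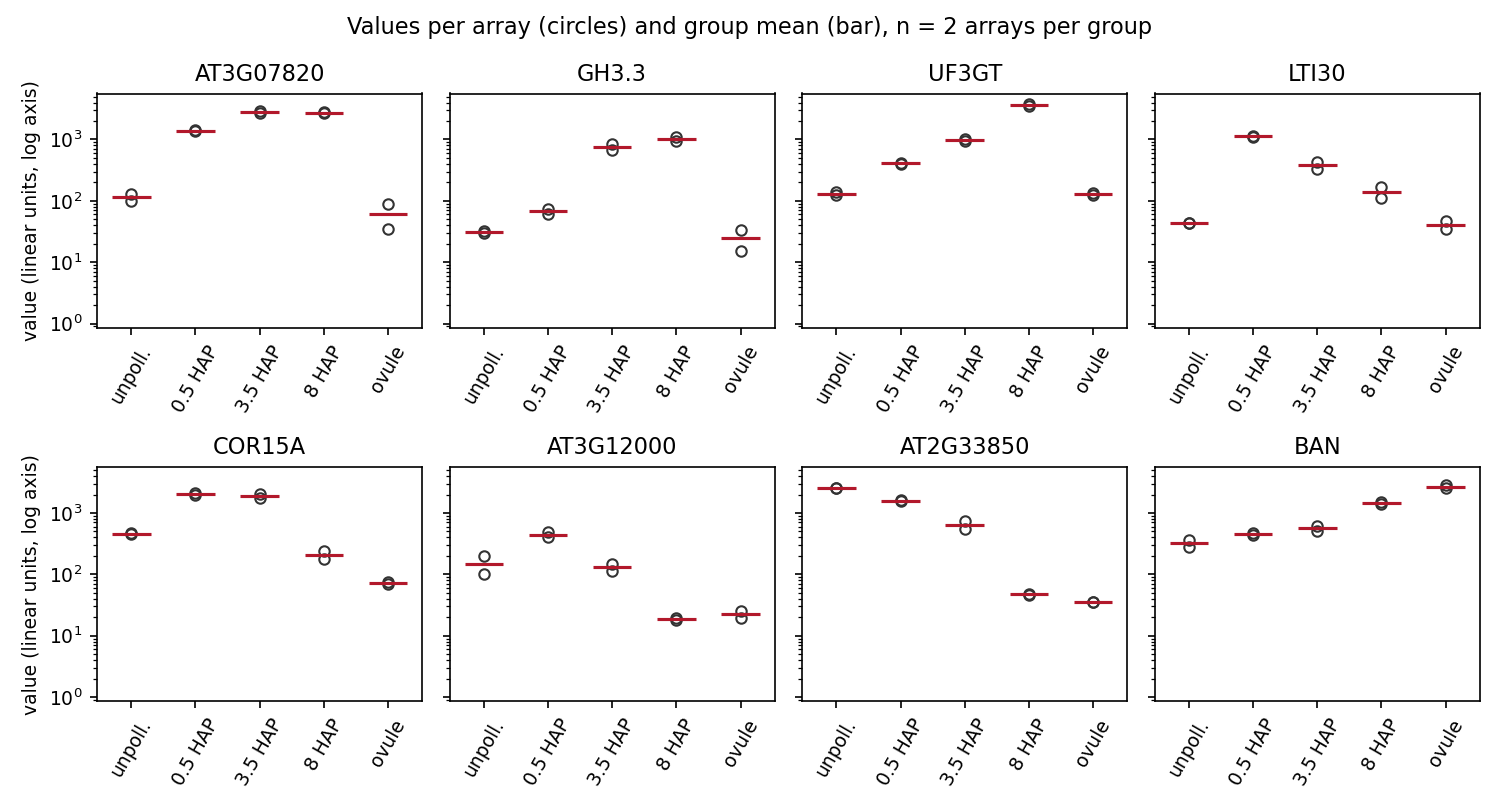
Values of 8 genes on each array (circles) with the mean of the 2 arrays (bar), in linear units on a log axis, for the 5 groups. GH3.3 lay at 67.1 at 0.5 HAP and 759.7 at 3.5 HAP, COR15A at 1867 at 3.5 HAP and 206.9 at 8 HAP, and BAN was highest in ovules (2682).

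Steps between times were tested directly. From 0.5 to 3.5 HAP, 2 further genes of the S1 family rose, AT3G26870 by 11.2-fold, from 12.8 ± 1.08 to 308.7 ± 53.1 (SD, n = 2), and AT3G26880 by 6.28-fold. GH3.3 rose 9.32-fold, AT5G39580, a peroxidase, 9.22-fold, and AT3G19690, of the pathogenesis-related 1 family, 5.59-fold. The falls included orfX, a mitochondrial reading frame (5.68-fold), AT1G56660 (4.50-fold), AT3G01830, a calmodulin-like protein (4.48-fold), AT5G19880, a peroxidase (4.12-fold), and the plastid gene rpl20 (3.53-fold). In the pollen list 4 of 7 genes rose by limma, ANX1 of them within the background level, and none fell. When adjusted over the list alone 5 rose. The list passed camera at adjusted p = 6.36e-06, and at adjusted p = 0.0454 with an estimated correlation. Of the 4, AT4G39110 missed the threshold without 0.5 HAP replicate 1 or 2 (adjusted p = 0.0678 and 0.0583) or 3.5 HAP replicate 2 (adjusted p = 0.0749). Of 7 measured auxin genes only GH3.3 passed. The list did not pass camera (adjusted p = 0.0587, or adjusted p = 0.367 with an estimated correlation). Leaving out 3.5 HAP replicate 1 or either ovule array changed the former outcome. OPCL1 fell 2.47-fold. This step held 3228 changed probe sets, 1181 up and 2047 down, the fewest of the 6 comparisons; the total was 1709 with arrays centred on the reference genes, 5895 with only these 2 groups in the fit, and 982 or 1338 without 0.5 HAP replicate 1 or 2 and 1381 or 1412 without 3.5 HAP replicate 1 or 2. The share of rises was 36.6% as deposited, 48.2% after quantile normalization and 48.5% with arrays centred on the reference genes.

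From 3.5 to 8 HAP the anthocyanin genes AT4G14090 (8.58-fold) and AT5MAT (5.07-fold) rose, with ASPGB1, an asparaginase (5.16-fold), AT5G47350 (5.51-fold) and orfX (6.60-fold). AT2G33850 fell 10.3-fold, COR15A 8.50-fold, AT1G72290 7.92-fold, AT1G30795 5.91-fold and AT1G70720 5.61-fold. In the stigma and style list CES (3.80-fold), AT3G12000 (4.18-fold, within the background level) and ARPN (2.08-fold) fell, with a list adjusted p = 0.00873, or adjusted p = 0.212 with an estimated correlation. In the pollen list 4 of 7 genes rose and 0 fell, and the list did not pass camera (adjusted p = 0.0985, or adjusted p = 0.212 with an estimated correlation). Of the 4, AT5G45840 missed the threshold after quantile normalization (adjusted p = 0.0562). All 3 gibberellin receptors fell (adjusted p = 0.00271, or adjusted p = 0.187 with an estimated correlation). All 5 photosynthesis genes fell (adjusted p = 0.00193, or adjusted p = 0.212 with an estimated correlation), but only 2 of them with arrays centred on the reference genes. That centring moved the median log2 difference over all probe sets from 0.051 to 0.038, so it did not shrink the falls. Of the 3 reference genes 1 was itself called lower in this step. RCA missed the threshold without 3.5 HAP replicate 1 (adjusted p = 0.0579) or 8 HAP replicate 1 (adjusted p = 0.0627), and PSAE-1 without any 1 of the 4 arrays (adjusted p = 0.0648 to 0.104). In the touch and wound list WRKY6 and STZ fell, and 4 of 4 when adjusted over the list alone (list adjusted p = 0.0111, or adjusted p = 0.187 with an estimated correlation). WRKY6 missed the threshold without 8 HAP replicate 2 (adjusted p = 0.054), and STZ without 3.5 HAP replicate 2 or 8 HAP replicate 1 or 2 (adjusted p = 0.215, 0.1 and 0.11). In total 7134 probe sets changed, 4310 up and 2824 down. The share of rises was 60.4% as deposited, 50.5% after quantile normalization and 59.3% with arrays centred on the reference genes. The count was 4270 with arrays centred on the reference genes, 4299 or 3983 without 3.5 HAP replicate 1 or 2, and 4146 or 3563 without 8 HAP replicate 1 or 2.

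Over the whole pistil time course 11966 probe sets passed limma's F test, of which 1427 differed at least 2-fold from unpollinated pistils at some time. The calls at different times overlapped: 1937 probe sets rose and 2199 fell at both 0.5 and 3.5 HAP, against 455.4 and 568.5 for independent lists. At 3.5 and 8 HAP 1919 rose and 2127 fell in both, and at 0.5 and 8 HAP 2290 and 2200. Groups simulated without change against shared controls gave a mean overlap of at most 0.05, but such groups yield almost no adjusted calls, so this value sets no level for the overlap of real changes. The log2 differences at 0.5 and 3.5 HAP correlated at r = 0.79 across probe sets, where unchanged groups gave 0.50; their covariance was 0.149 against a simulated 0.00628. With a different unpollinated array in each comparison, a split added after the data were seen, the covariance was 0.132 or 0.14 (r = 0.64 or 0.71); a handling shared by both unpollinated pools stays in it. The overlap counts were not split, so part of their excess may come from the shared arrays.

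Genes of the 2 organelle genomes were grouped after the data were examined, from the gene table or from symbols. A gene missing from that table was counted as mitochondrial if its symbol began with nad, cox, ccb, matR or orfX. All 16 mitochondrial genes have such symbols, so mitochondrial genes with other names may be left out. Of 16 mitochondrial genes 13 fell at 0.5 HAP, 15 at 3.5 HAP and 14 at 8 HAP, with median log2 differences of -1.43, -1.97 and -1.47. AT2G07718, AT2G07707 and AT2G07722 lie in the nuclear copy of the mitochondrial genome, so their signal may be shared with it. In ovules, which came from unpollinated pistils, 11 of the 16 mitochondrial genes were also lower (median -0.68; camera adjusted p = 0.002, or adjusted p = 0.528 with an estimated correlation). Of 69 plastid genes 30 rose at 0.5 HAP (median 0.35), and 30 fell from 0.5 to 3.5 HAP. The mitochondrial set passed camera at the 3 times (adjusted p = 2.01e-08, 5e-10 and 1.61e-07), but not with an estimated correlation (adjusted p = 0.819, 0.69 and 0.884). Without unpollinated replicate 2, the array with the higher 3' to 5' ratios, the mitochondrial medians were -0.97, -1.58 and -1.13. The 3.5 HAP arrays, with the lowest mitochondrial median, stood apart from the other pollinated pistils in control probe sets. Their 25S ribosomal RNA control was at 4962 and 5286, against 6371 to 7524 on the other pistil arrays, and their hybridization controls had mean log2 values of 10.69 and 10.52, against 9.84 to 9.97 at 0.5 and 8 HAP and 10.19 and 10.53 in unpollinated pistils.

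**Figure D3:**
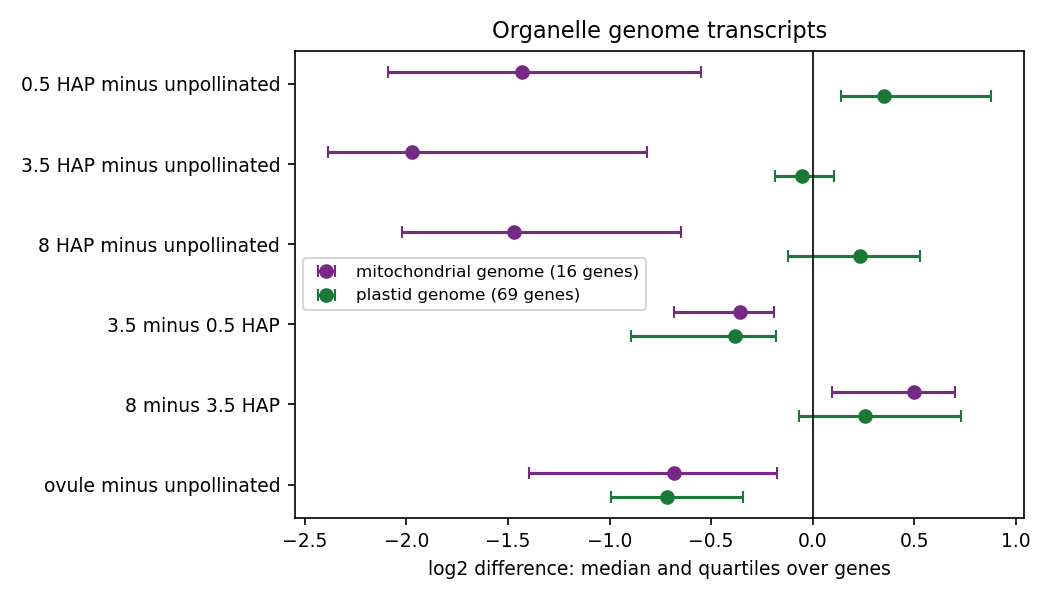
Median log2 difference (points) and quartiles (bars) over 16 mitochondrial and 69 plastid genes in the 6 comparisons. The mitochondrial medians lie below 0 at all 3 times against unpollinated pistils, and the plastid median is 0.35 at 0.5 HAP and -0.71 in ovules.

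The last comparison set ovules against whole unpollinated pistils. BAN was 8.10-fold higher in ovules (2682 ± 245 against 319.6 ± 63.4; SD, n = 2; adjusted p = 9.31e-09), DELTA-VPE, a protease of the seed coat, 7.47-fold, and INO 3.15-fold. The egg cell genes EC1.2 (log2 1.74) and EC1.5 (log2 1.68) were higher, as was FER, a receptor kinase placed in the embryo sac list (1.63-fold). Of 6 embryo sac genes 4 were higher, AGL62 of them within the background level, as were 2 of 3 integument genes. Neither list passed camera (adjusted p = 0.0633 and 0.0698, or adjusted p = 0.199 for each with an estimated correlation). The outcome for the embryo sac list depended on unpollinated replicate 1. AT4G15750, of the invertase and pectinesterase inhibitor family, was 9.04-fold higher, and AT5G58400, AT3G57250, AT3G56610, AT5G46300, AT1G56100, AT1G12180, AT5G42955, AT3G05600 and AT5G22970 were between 5.09-fold (AT5G22970) and 7.83-fold (AT5G58400) higher. AT2G33850 was 49.4-fold lower, within the background level in ovules, BCAT4 36.4-fold and AT1G67865 by a log2 difference of -5.13, with AT1G67860, AT4G19430, AT3G28270, AT2G23540 and AT1G68570 lower by log2 differences between -4.15 (AT1G68570) and -4.78 (AT1G67860). All 5 photosynthesis genes were lower, RCA by 7.48-fold (list adjusted p = 1.81e-05, or adjusted p = 0.199 with an estimated correlation). Of 8 cell wall genes 5 were lower, XTH19 by 10.6-fold (adjusted p = 0.0105, or adjusted p = 0.199 with an estimated correlation). No pollen list gene was higher in ovules, and AT5G45840 was 1.19-fold lower within the background level, a call lost after quantile normalization (adjusted p = 0.0783), with a pseudocount of 64 (adjusted p = 0.0672), with only the 2 groups in the fit (adjusted p = 0.0963), and without unpollinated replicate 1 (adjusted p = 0.101) or ovule replicate 2 (adjusted p = 0.129).

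In ovules 11746 probe sets differed from unpollinated pistils, 6743 higher and 5003 lower, with 778 higher and 1622 lower at least 2-fold; without unpollinated replicate 2 the total was 11276. The share of higher calls was 57.4% as deposited, 61.2% after quantile normalization and 62.9% without the dimmest 40% of probe sets. It was 40.5% with arrays centred on the reference genes, of which AT4G34270 was 1.53-fold higher in ovules. Among probe sets lower in ovules 1830 fell at 8 HAP, against 941.4 for independent lists, and among those higher in ovules 1876 rose at 8 HAP, against 1329. Among probe sets lower in ovules 1047 rose at 0.5 HAP, against 777.8, and 1014 at 3.5 HAP, against 644.3, beside 1207 and 1242 that fell, against 735.5 and 850.6. Among those higher in ovules 906 fell at 0.5 HAP, against 991.4, and 1003 at 3.5 HAP, against 1146, beside 1231 and 972 that rose, against 1048 and 868.3. At 0.5 and 3.5 HAP probe sets lower in ovules exceeded the independent value in both directions, so those excesses alone show no shared direction. The log2 differences of ovules correlated at r = 0.11 with those of 0.5 HAP and at r = 0.06 with those of 3.5 HAP. With a different unpollinated array in each comparison, r was 0.03 or 0.09 for 0.5 HAP and -0.02 or 0.06 for 3.5 HAP. The log2 differences of ovules and of 8 HAP correlated at r = 0.20 across probe sets, below the 0.50 of simulated unchanged groups, with a covariance of 0.0708 against 0.0063, or of 0.0516 or 0.0634 with a different unpollinated array in each comparison.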

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

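All tests of explanations in this part, and their bounds, were chosen after the results were seen. Several genes lay above unpollinated pistils at some times and below them at others. Their log2 differences from unpollinated pistils follow for 0.5, 3.5 and 8 HAP in turn. They were 2.105, 1.972 and -1.115 for COR15A, and 1.539, -0.126 and -2.188 for AT3G12000. For AT1G44970 they were 1.098, 0.4632 and -1.407, and for orfX 0.9446, -1.562 and 1.161. Limma's test of the step between 3.5 and 8 HAP does not itself test a change of sign. For each gene its adjusted p was smaller than that of the step from 0.5 to 3.5 HAP. COR15A, 4.30-fold above unpollinated pistils at 0.5 HAP, changed by -3.09 on the log2 scale between 3.5 and 8 HAP (adjusted p = 1.88e-07). AT3G12000 changed by -2.06 (adjusted p = 0.00013) and AT1G44970 by -1.87 (adjusted p = 4.59e-05); the latter lies outside the rule for named genes and was named after its values were seen. The mitochondrial reading frame orfX changed by 2.72 in the same step (adjusted p = 6.6e-05), having been lower at 3.5 HAP than at 0.5 HAP. Among control probe sets, which no comparison used, both ovule arrays lay above both unpollinated arrays for the 25S ribosomal RNA control (mean 9216) and for the hybridization controls (mean log2 10.74). The 3.5 HAP arrays stood apart in the other direction for the 25S control (4962 and 5286), below all other arrays.

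Mitochondrial transcripts were lower at all 3 times than in unpollinated pistils, and also in ovules (median -0.68, or -0.44 without unpollinated replicate 2 and -1.01 without replicate 1). One odd unpollinated array cannot account for it all: without either of them in turn, at least 12 of the 16 genes were still called lower at each time, although the median at 0.5 HAP was -0.97 without replicate 2 and -1.76 without replicate 1. A different yield of organelle transcripts as a class, if it acted alike on both genomes, would have moved plastid transcripts alike. Whether it acts alike was not tested. Their median lay above the mitochondrial one by at least 1.70 on the log2 scale at each time. A yield acting alike on both genomes therefore cannot alone account for the lower mitochondrial values at the 3 times. One beside other changes, or one that differs between the genomes, stays open. Between times the mitochondrial and plastid medians moved alike, by -0.36 and -0.38 from 0.5 to 3.5 HAP. From 3.5 to 8 HAP they moved by 0.50 and 0.26, so for both steps a class yield is not excluded. In ovules the medians were alike too (-0.71 for plastid genes), so there a class yield is not excluded. All 4 other groups thus lie below the same 2 unpollinated arrays, and ovules had met no pollen, so a fall after pollination cannot account for the ovule values; a shared handling of both unpollinated pools stays open for every group, and for the 3 times a fall after pollination does too, since the labels give no batch.

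Pollen list transcripts were higher at 3.5 than at 0.5 HAP. A larger share of pollen RNA could multiply all of them by one factor, and over the 6 usable members the median factor of the gain over unpollinated pistils was 2.50. For 2 members, TUA1 (1.425) and AT2G21480 (1.103), the 95% simulation interval excluded that factor, which taken alone speaks against it. The limit to members above background and with a low unpollinated level, which sets both aside together with ANX1 (3.265, at 115.7 at 3.5 HAP), was added only after that count was seen: TUA1 was already at 476.4 in unpollinated pistils and AT2G21480 stayed at background level. The 3 members left, ANX2 (2.653), AT4G39110 (2.344) and AT5G45840 (2.681), are too few to decide. The median factor was also taken from the 6 members themselves, without its own error, and lies between those of AT4G39110 and ANX2. Those 2 could hardly exclude it, so the restricted count decides nothing. A larger pollen share and changes within pollen tubes therefore cannot be told apart.

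GI was lower at 8 than at 3.5 HAP, as was the photosynthesis list (adjusted p = 0.00193), but the list's call is lost with an estimated correlation (adjusted p = 0.212), and only 2 of its 5 genes kept theirs with arrays centred on the reference genes. That centring did not shrink the falls. The hour of collection may contribute, but GI, with a log2 difference of -0.87, was the only measured clock gene of 18, and the labels give no hour. The hour and the time after pollination cannot be told apart here, and a response to pollination stays open, untested.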

How the results depend on the processing

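Chosen after the data were seen were leaving out an array for the gene lists, an estimated correlation for the families, the crossed ovule numbers and the split unpollinated arrays; the other settings were fixed before. With arrays centred on the reference genes, calls fell to 4360 at 0.5 HAP, 4091 at 3.5 HAP, 1709 between 0.5 and 3.5 HAP and 4270 between 3.5 and 8 HAP; 3 genes set that scale and the cause was not tested. With only the 2 groups compared in the fit, the step from 0.5 to 3.5 HAP gave 5895 calls. With a pseudocount of 64, which shrinks folds of dim genes, 163 probe sets fell at least 2-fold at 3.5 HAP and 111 rose at least 2-fold between 3.5 and 8 HAP. Without the dimmest 40% of probe sets, fewer were tested and the rises of at least 2-fold numbered 314 at 3.5 HAP, 410 at 8 HAP and 70 between 0.5 and 3.5 HAP. Leaving out 1 array, where the lone array is assumed to vary like the others, gave 3723 to 7318 calls at 0.5 HAP, 3981 to 8157 at 3.5 HAP, 5610 to 9111 at 8 HAP, 982 to 4469 between 0.5 and 3.5 HAP and 3563 to 8571 between 3.5 and 8 HAP. The other counts of changed probe sets stayed within 1.5 times, 7 overlap counts moved further when 1 of the 2 calls was left unadjusted, and the named genes chosen for size kept direction and threshold in 1953 of 1953 values. Those named genes were chosen here as the largest calls with the arrays of the 2 groups apart. Their count was therefore largely set by that choice and is no test of robustness. With each list counted once per comparison, 11 list results lost the threshold with an estimated correlation, as given beside them. The pollen list kept it at 3.5 HAP, at 8 HAP and in the step from 0.5 to 3.5 HAP. In the step from 3.5 to 8 HAP that list passed with neither correlation. Signal near background limits the dim genes.

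The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.07 to 0.11 between groups, except -0.32 between unpollinated pistils and ovules. With a replicate block 6362 probe sets were called at 0.5 HAP, 6285 at 3.5 HAP, 8333 at 8 HAP and 11398 in ovules. Crossing the ovule numbers gave 11809 calls.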

Other observations

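The families in this part were formed from gene symbols after the data were examined, and none of their calls held with an estimated correlation. At 3.5 HAP 6 of 14 SWEET sugar transporter genes rose and 1 fell (camera adjusted p = 0.0157; adjusted p = 0.529 with an estimated correlation), and 4 of 6 WRKY genes rose (adjusted p = 0.00768; adjusted p = 0.529 with an estimated correlation). Of these 4, WRKY6, WRKY22 and WRKY53 are the risen genes of the touch and wound list, so the family is no separate evidence. Of 8 ATG autophagy genes 5 fell at 0.5 HAP and 7 at 8 HAP, while 3 rose between 0.5 and 3.5 HAP; with an estimated correlation the adjusted p was 0.819, 0.884 and 0.619. In ovules 7 of 8 SEC secretion genes were higher (adjusted p = 0.0416; adjusted p = 0.416 with an estimated correlation), but 3 of 8 with arrays centred on the reference genes. Of 47 UGT glycosyltransferase genes 18 were lower in ovules and 5 higher (adjusted p = 0.002; adjusted p = 0.238 with an estimated correlation).

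A heat shock list was added after ATHSP22.0, AT5G48570 and AT4G21870 had been seen among the changed genes. At 3.5 HAP 8 of its 14 measured genes fell and 3 rose (camera adjusted p = 0.185; adjusted p = 0.853 with an estimated correlation). In ovules, from unpollinated pistils, 8 were lower and 2 higher (adjusted p = 0.025; adjusted p = 0.55 with an estimated correlation). The members went both ways, as a pair chosen after their values were seen shows: AT1G53540, a small heat shock protein, was at 685.7 in unpollinated pistils and 169.6 at 3.5 HAP, whereas AT3G09440, of the Hsp70 family, was at 442.8 and 1436.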
